A study of Rattus norvegicus with 4 samples.

How the data were processed

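RNA of neonatal rat ventricular myocytes was sequenced in 4 libraries, 2 from cells given vehicle and 2 from cells given 1 µM carfilzomib for 24 h, per the labels. Groups and replicate numbers were taken from the sample titles. In the deposited tables the columns of the untreated side are named as a control, and they were taken as the vehicle samples of the same number, since vehicle is the only control in the labels. Libraries followed a standard protocol of the sequencing provider, and strand and read length are not given in the sources used here.

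The authors deposited estimated counts per gene, not normalised, of which about 29% of genes per library carry decimals (more than 1e-06 from a whole number), per the file headers and the values. The tool that produced the decimals is not given in the sources used here. Per the submitters' processing notes, the tools were FastQC 0.11.8, cutadapt 2.0, HISAT, Bowtie2, featureCounts 1.6.0, DESeq2 and R 3.3.2, with the rat build Rnor_6.0; their order and roles are not given. The authors also deposited FPKM values, which served only to derive the gene length by which the authors had divided. A table of the authors' comparison holds log2 fold changes with a p-value and q-value per gene from DESeq2, per the file headers. It lists 6063 genes, all with a q-value up to 0.0499, and it is quoted only as the authors' deposited table. In the expression table, 10 columns were not used here. Apportioned reads can move the values of near-identical genes towards each other or apart.

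The estimated counts were rounded to whole numbers. Totals were 18757766 and 18736096 counts for vehicle and 18884362 and 18655499 for carfilzomib, and the 10 most abundant genes took 7.09%, 7.12%, 4.78% and 4.66% of them. Every row had a gene name, and 7 symbols that stand for more than 1 gene ID were kept apart by their IDs. The replicates of each group differed by more than sampling noise, with a chi-square per degree of freedom of 3.32 for vehicle and 2.99 for carfilzomib, so they were kept as separate libraries.

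Genes were tested with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. Genes passed filterByExpr, with a minimum count of 10 and a minimum total of 15, which left 14519 genes. TMM factors lay between 0.987 and 1.01, the common biological coefficient of variation was 0.0465, and the robust quasi-likelihood F test compared the groups with Benjamini-Hochberg adjustment at 0.05. Standard errors are the absolute log2 fold change divided by the square root of F. CPM are TMM-normalised, and values after ± are the SD over 2 libraries unless named SE.

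Before the data were examined, 30 gene lists with 606 entries were fixed, of which 596 were matched to the table. Of these, 4 were matched through a RefSeq gene table, which held 17402 of the table's gene IDs. A further 7 entries led to a row already matched in their list, and 3 were not matched. Among the 7 was Hspa1b, since Hspa1a had been matched by its gene ID to the row of that name. Some genes stand in more than 1 list, among them Myh7, Ankrd1, Cryab, Des and Slc7a11, so the lists are not independent. Each list was counted by call, over all genes tested and over the list alone. Each was tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. With 2 residual degrees of freedom in that fit an estimated correlation is poorly determined. Camera compares a list with the other genes, and fry tests whether its members move on balance in 1 direction.

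The genes named in the text followed a rule fixed at the same time. It takes Senp1 and Ddx17; the fixed genes Nppa, Nppb, Myh6, Myh7, Ryr2, Atp2a2, Hmox1, Sqstm1, Ddit3, Psmd12 and Dnm1l; and the 8 largest rises and 8 largest falls among called genes with groups that do not overlap, a mean of at least 10 CPM and a full gene symbol. From each list it takes the 2 called members with the largest change in the majority direction and the 1 largest in the other direction, with a mean of at least 10 CPM. It names 102 genes, 31 of them with split reads, and 3 of the 102 are not reported here. Other genes were chosen after their values were seen, and the text says so.

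The scripts were tested on simulated counts for 14270 genes with the mean levels of the vehicle libraries and the real library sizes. In them 50 genes were changed at each fold size. For this comparison edgeR recovered 58% of genes changed 1.25-fold, 82% at 1.5-fold, 90% at 2-fold and 96% at 4-fold, and 24 of 187 calls, 12.8%, were false. DESeq2 recovered 38%, 64%, 80% and 96%, with 10 of 149 calls false, 6.71%. In the data 60.7% of tested genes were called, a far larger share than was changed in the simulation. Its rates of recovery and of false calls therefore need not hold for the data.

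The alternatives were DESeq2 1.42.0, limma-voom, RLE factors, library size alone, no low-count filter, a stricter filter of 1 CPM in 2 libraries with a total count of at least 50, a replicate block, each of the 4 libraries left out, a test against a fold change of 1.5, and the estimated correlation. Leaving out a library leaves its group with 1, which is then assumed to vary like the other group. After the data were seen, a fit over genes with whole counts in all libraries and a fit with Myh6 and Myh7 summed were added. Splits of the libraries by chance were not counted, since each group has 2 libraries.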

Results

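Ventricular heart muscle cells of newborn rats were treated in culture with carfilzomib, an irreversible inhibitor of the proteasome used against multiple myeloma, and their RNA was sequenced. The cells came from Sprague Dawley rats of 1 to 3 days of age and grew with 0.1 mM bromodeoxyuridine, which holds back cells other than cardiomyocytes. There were 2 vehicle libraries and 2 libraries treated with 1 µM carfilzomib for 24 h. The 2 vehicle libraries held 18757766 and 18736096 estimated counts and the 2 carfilzomib libraries 18884362 and 18655499, over 18699 genes. Nothing in the labels says whether the 2 libraries of a group came from separate cultures or animals, so p-values measure only the spread between these libraries, which may be technical. About 29% of the genes in each library had an estimated count with decimals (more than 1e-06 from a whole number). This may mean that part of their reads was apportioned and not counted whole, but the source of the decimals is not given. Genes with decimals in at least 1 library are called genes with split reads, and their values are less certain where a near-identical gene exists. Positions in the genome were not used here.

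The comparison of carfilzomib with vehicle addresses how the drug harms heart cells, and the study's title names SENP1 and DDX17. Carfilzomib changed the level of 8812 of 14519 genes tested, 60.7%, with 4444 higher and 4368 lower. Most tested genes of the proteasome, of the antioxidant response and of autophagy rose, while most tested genes of the sarcomere, calcium handling, proliferation and extracellular matrix fell. A change of at least 2-fold was reached by 543 genes that rose and 1072 that fell, and the median absolute log2 fold change of the changed genes was 0.50. Calls were made with edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p under 0.05, and all fold changes are carfilzomib over vehicle. Of 30 gene lists fixed before the data were examined, camera with a preset correlation of 0.01 called 7 higher and 12 lower against the other genes. With a correlation estimated from the 4 libraries 0 lists passed, 9 had an unadjusted p under 0.05, and fry gave 22 lists an unadjusted p under 0.05. The number of members past the threshold was the same when adjusted over the list alone in 26 of the 30 lists, and the 4 exceptions are given with their lists.

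Senp1 (gene ID 300193), which encodes a protease that removes SUMO from proteins, fell from 50.2 ± 1.05 to 39.3 ± 1.04 CPM (normalised counts scaled to library size; mean ± SD, n = 2 per group). Its log2 fold change was -0.35 ± 0.06 (SE), with an edgeR adjusted p of 1.44e-04. Ddx17 (gene ID 315133), which encodes a DEAD-box RNA helicase, rose from 129 ± 1.53 to 146 ± 4.81 CPM. Its log2 fold change was 0.18 ± 0.05 (SE), with an edgeR adjusted p of 0.00312, and both treated libraries lay above both vehicle libraries. Without carfilzomib replicate 1 the log2 fold change of Ddx17 was 0.15 and its edgeR adjusted p 0.0755. Of 19 tested genes of the SUMO pathway 6 rose, 2 fell and 11 did not pass, with a median log2 fold change of 0.02. Ranbp2, a nuclear pore protein with SUMO ligase activity, rose by a log2 fold change of 1.11. The camera adjusted p of the SUMO list was 0.57. Of 27 DEAD-box helicases 13 rose, 4 fell and 10 did not pass, with a median of 0.14 and a camera adjusted p of 0.174. Ddx46 rose by 0.65 and Ddx10 by 0.54 on the log2 scale, while Ddx59 had -0.36. Under DESeq2 the adjusted p of Ddx59 was 0.0949, and without the low-count filter the camera adjusted p of the helicase list was 0.0364. In the main fit with an estimated correlation, the helicase list had a camera adjusted p of 0.652.

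All 34 tested genes of the proteasome subunit list rose, with a median log2 fold change of 1.26 and a range from 0.45 to 2.30. The list also holds Pomp, a proteasome maturation factor. Psmb3, a subunit of the 20S core, rose 4.92-fold from 98.3 ± 5.04 to 484 ± 0.29 CPM. Psmd14, the deubiquitinating subunit of the 19S cap, rose by 1.93 on the log2 scale, and Psmd12, another subunit of the cap with split reads, by 1.18 ± 0.04 (SE). For the proteasome list camera gave an adjusted p of 4.4e-87, against an adjusted p = 0.1405 with an estimated correlation. Of 14 ubiquitin genes and ubiquitin ligases of muscle 9 rose, 2 fell and 3 did not pass; 10 rose when adjusted over the list alone. Uchl1, a ubiquitin hydrolase abundant in neurons, rose 6.84-fold from 148 ± 17.2 to 1011 ± 26.7 CPM, and Usp14, a deubiquitinase bound to the proteasome, had a log2 fold change of 1.39. Stub1, a chaperone-dependent ubiquitin ligase with split reads, fell by 0.30 on the log2 scale. The ubiquitin list had a median of 0.34 and a camera adjusted p of 7.22e-06, with adjusted p = 0.1405 with an estimated correlation. Over genes without split reads alone its median was 0.89.

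**Figure D1:**
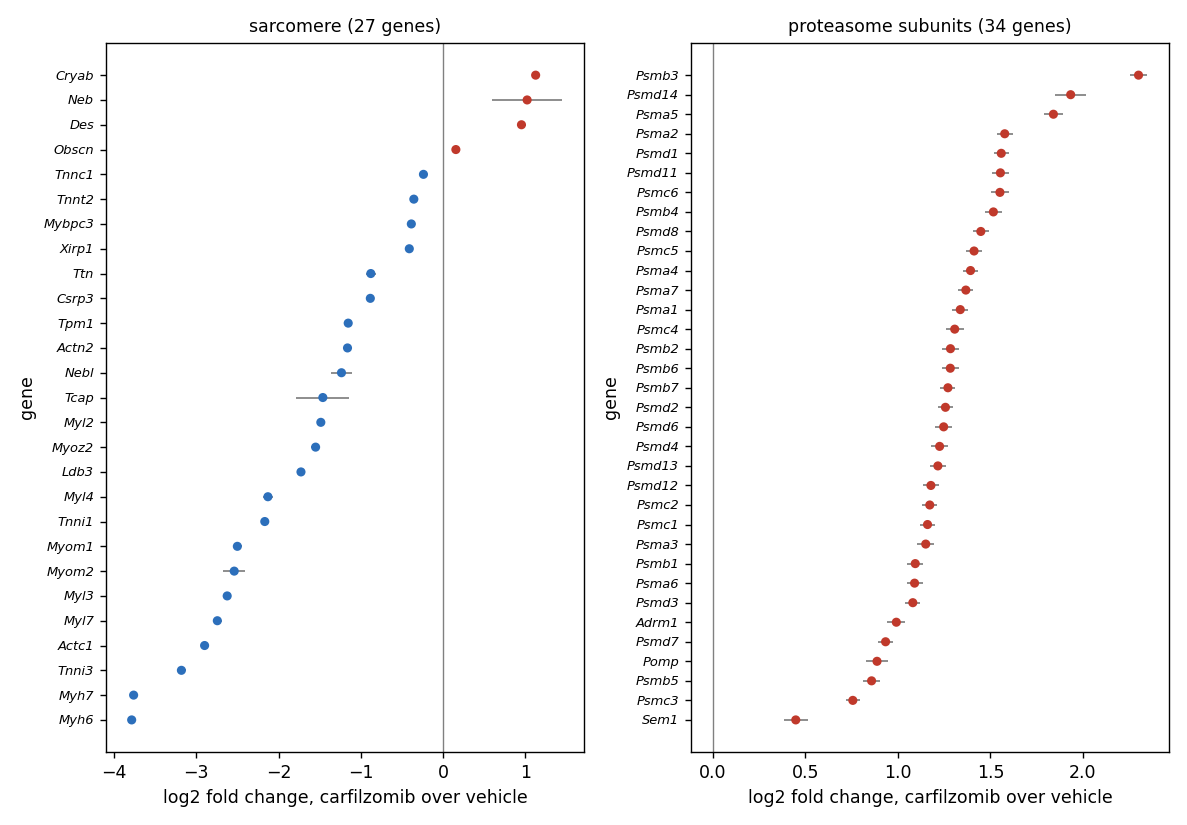
Log2 fold change, carfilzomib over vehicle, of the 27 sarcomere genes on the left and the 34 genes of the proteasome subunit list on the right, with 1 gene per line. Points are edgeR estimates, bars are their standard errors, red is higher and blue lower at an adjusted p under 0.05. All 34 proteasome genes lie above 0, between 0.45 and 2.30, and 23 of the 27 sarcomere genes lie below 0, down to -3.79.

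Of 20 genes of autophagy and aggregate clearance 15 rose, 2 fell and 3 did not pass, with a median of 0.36. Sqstm1, the p62 receptor that carries ubiquitinated cargo to autophagosomes, rose 4.85-fold from 331 ± 22.6 to 1603 ± 0.43 CPM. Gabarapl1, an autophagosome membrane protein, rose by 1.73 on the log2 scale, while Map1lc3a fell by 0.67. The autophagy list's camera adjusted p was 5.19e-11, with adjusted p = 0.1405 with an estimated correlation, and its median over genes without split reads was 0.59. Of 24 cytosolic heat shock proteins and co-chaperones 14 rose, 3 fell and 7 did not pass, with a median of 0.29. The small heat shock proteins Hspb8 and Cryab rose by 1.64 and 1.13, and Dnajb1, a co-chaperone of Hsp70, fell by 0.54. The heat shock list's camera adjusted p was 1.43e-05, with adjusted p = 0.1405 with an estimated correlation.

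Of 20 antioxidant genes controlled by NRF2 16 rose, 2 fell and 2 did not pass, with a median log2 fold change of 0.63. Osgin1 rose by 2.72 and Gsr, glutathione reductase, by 1.59, while Slc7a11, a cystine transporter gene with split reads, fell by 1.22. Hmox1, haem oxygenase, was at 127 ± 8.43 CPM with vehicle and 122 ± 3.95 CPM with carfilzomib. Its log2 fold change of -0.06 ± 0.05 (SE) did not pass, with an edgeR adjusted p of 0.36, and it was -0.12 without vehicle replicate 1, 0.01 without vehicle replicate 2 and -0.02 without carfilzomib replicate 1. The NRF2 list's camera adjusted p was 5.36e-14, with adjusted p = 0.1405 with an estimated correlation.

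Of 24 targets of ATF4 and CHOP in the integrated stress response 16 fell, 4 rose and 4 did not pass, with a median of -0.58. Chac1, a glutathione-degrading enzyme, fell by 2.04 and Trib3, a pseudokinase, by 1.97 on the log2 scale. Gdf15, a stress-induced cytokine gene with split reads, rose by 1.77. Ddit3, which encodes CHOP and has split reads, fell from 43.7 ± 0.19 to 39.0 ± 1.19 CPM with a log2 fold change of -0.16 ± 0.06 (SE) and an edgeR adjusted p of 0.0297. The call of Ddit3 was lost when any 1 of the 4 libraries was left out, with edgeR adjusted p from 0.0632 to 0.229 and log2 fold changes from -0.19 to -0.13. For the integrated stress response camera gave an adjusted p of 5.43e-07, with adjusted p = 0.1405 with an estimated correlation. Of 20 chaperones and degradation factors of the endoplasmic reticulum 11 fell, 4 rose and 5 did not pass, with a median of -0.23. Herpud1 fell by 0.85 and Xbp1, a transcription factor of the unfolded protein response, by 0.79, while Pdia3, a gene with split reads, rose by 0.37. Its camera adjusted p was 0.0261, with adjusted p = 0.416 with an estimated correlation, and 0.0652 without vehicle replicate 1, where the median was -0.22. Matrix and fibroblast markers had a median of -0.57 in the same libraries.

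Of 19 p53 targets and apoptosis genes 9 rose, 4 fell and 6 did not pass, with a median of 0.13. Mdm2, the ubiquitin ligase of p53, rose by 1.22 and Cdkn1a, a cell cycle inhibitor, by 0.74, while Apaf1, a gene with split reads, fell by 0.35. The list's camera adjusted p was 0.0203, with adjusted p = 0.208 with an estimated correlation. It was 0.0764 with limma-voom and 0.0563 without the low-count filter. Its median was 0.21 without vehicle replicate 1 and 0.39 over genes without split reads, and Apaf1 was at -0.22 without vehicle replicate 1.

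Of 27 sarcomere genes 23 fell and 4 rose, with a median log2 fold change of -1.46. Myh6, the fast cardiac myosin heavy chain, fell 13.8-fold from 9820 ± 280.2 to 712 ± 3.64 CPM (mean ± SD, n = 2). Myh7, the slow heavy chain, fell 13.6-fold from 3618 ± 131 to 267 ± 8.25 CPM. Their edgeR adjusted p was 8.19e-17 and 9.55e-17, and both genes have split reads, as has Tnni3, cardiac troponin I, which fell by 3.18 on the log2 scale. With the counts of Myh6 and Myh7 summed, the log2 fold change was -3.78. Actc1 and Tnnt2, chosen after their values were seen, had log2 fold changes of -2.90 and -0.36. The genes that rose included Cryab, at 1272 ± 41.8 CPM with vehicle and 2776 ± 25.1 CPM with carfilzomib, and Des, the intermediate filament desmin, at 1447 ± 84.3 and 2802 ± 158 CPM. The sarcomere list's camera adjusted p was 8.01e-68, with adjusted p = 0.1405 with an estimated correlation. Markers of fibroblasts, smooth muscle cells and macrophages had medians of -0.57, -1.03 and -2.09 in the same libraries.

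Of 25 genes of calcium handling and ion channels 21 fell, 1 rose and 3 did not pass, with a median of -0.63. Casq2, which binds calcium in the sarcoplasmic reticulum, fell by 2.16 and Fxyd1, a regulator of the sodium pump, by 2.15 on the log2 scale. Ryr2, the calcium release channel, fell from 219 ± 21.3 to 89.3 ± 3.36 CPM, and Atp2a2, the calcium pump SERCA2, from 1822 ± 16.2 to 885 ± 3.06 CPM; both have split reads. Camk2d, a gene with split reads, had a log2 fold change of 0.17 with an edgeR adjusted p of 0.0132. That edgeR adjusted p was 0.0533 without vehicle replicate 2, with a log2 fold change of 0.15, and 0.0936 without carfilzomib replicate 1, with 0.16. Calcium handling had a camera adjusted p of 1.16e-11, with adjusted p = 0.192 with an estimated correlation, and its median over genes without split reads was -1.17.

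Of 15 cardiac transcription factors 11 fell, 3 rose and 1 did not pass, with a median of -0.35. Srf, which drives actin and contractile genes, fell by 1.19 and Ankrd1 by 0.98 on the log2 scale, while Prox1, a gene with split reads, rose by 0.43. Against the other genes the camera adjusted p was 5.4e-04, with adjusted p = 0.208 with an estimated correlation. Of 13 fetal and hypertrophic markers 9 fell, 2 rose and 2 did not pass, with a median of -0.49. The largest fall among them was that of Myh7, at -3.76, which also stands in the sarcomere list, and Ankrd1 stands in both lists of this paragraph. Ccn2, a matricellular growth factor, fell by 1.54 and Xirp2, an actin-binding repeat protein, rose by 2.11. Nppb, the B-type natriuretic peptide, fell by 0.52 ± 0.04 (SE) on the log2 scale. Nppa, the atrial natriuretic peptide, was at 4241 ± 172 CPM with vehicle and 4244 ± 199 CPM with carfilzomib, with an edgeR adjusted p of 0.986; its log2 fold change of 0.00 ± 0.04 (SE) ranged from -0.05 to 0.05 when 1 library was left out. The fetal list's camera adjusted p was 2.74e-09, with adjusted p = 0.1405 with an estimated correlation. In the same libraries the medians of fibroblast and smooth muscle markers were -0.57 and -1.03.

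**Figure D2:**
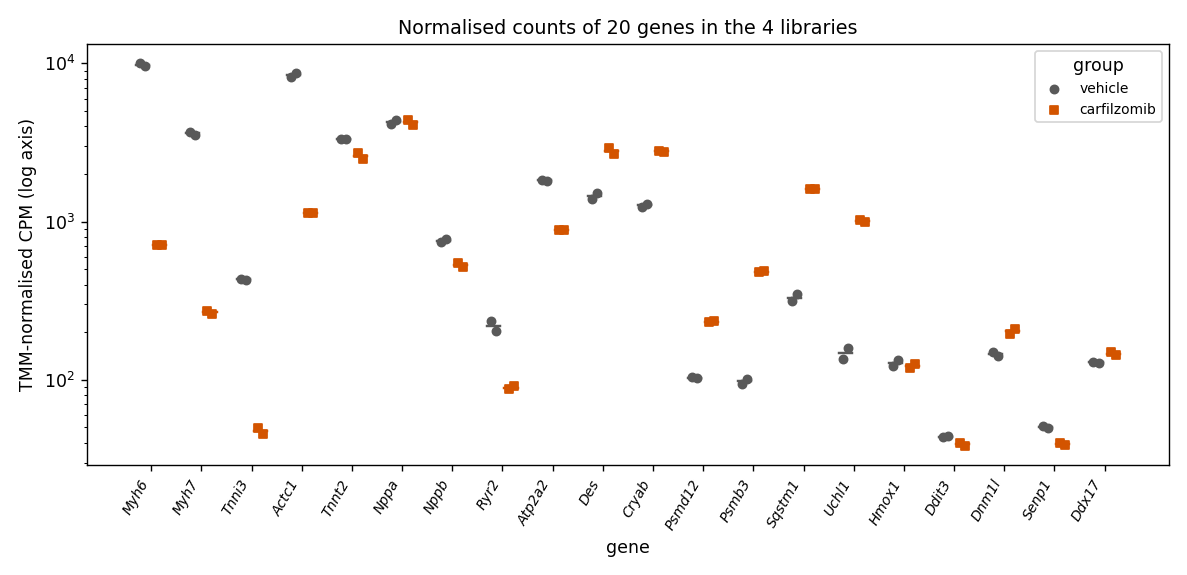
TMM-normalised CPM, on a log axis, of 20 genes in the 4 libraries, with vehicle as grey circles, carfilzomib as orange squares and a line at each group mean. Myh6 and Myh7 lie more than 13-fold lower with carfilzomib, Sqstm1 4.85-fold and Uchl1 6.84-fold higher, and the groups of Nppa and Hmox1 overlap.

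Lists of energy metabolism moved in both directions. Of 27 nuclear-encoded respiratory chain genes 20 fell, 1 rose and 6 did not pass, with a median of -0.33. Cox6a2, the muscle form of a cytochrome c oxidase subunit, fell by 1.11, Cycs, cytochrome c, with split reads, by 0.93, and Ndufa4 rose by 0.44. For the respiratory chain camera gave an adjusted p of 1.84e-05, with adjusted p = 0.224 with an estimated correlation. Of 15 genes of mitochondrial dynamics and mitophagy 9 rose, 1 fell and 5 did not pass, with a median of 0.21. The mitophagy receptors Bnip3 and Bnip3l rose by 1.30 and 0.50, the latter with split reads. Dnm1l, the fission GTPase DRP1, with split reads, rose from 146 ± 6.67 to 203 ± 10.6 CPM. Phb2 had a log2 fold change of -0.13 with an edgeR adjusted p of 0.0212, which was 0.107 without vehicle replicate 2 and 0.256 without carfilzomib replicate 2, with log2 fold changes of -0.10 in both cases. The list's camera adjusted p was 0.0408, with adjusted p = 0.416 with an estimated correlation. That camera adjusted p was 0.0652 without vehicle replicate 1, where the median was 0.25, 0.0516 with the stricter low-count filter and 0.133 over genes without split reads.

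Of 22 fatty acid oxidation genes 10 rose, 10 fell and 2 did not pass, with a median of 0.09 and a camera adjusted p of 0.928. Acadvl, an acyl-CoA dehydrogenase, rose by 1.47 and Ech1 by 1.10, while Fabp3, the heart fatty acid-binding protein, with split reads, fell from 355 ± 1.48 to 149 ± 2.18 CPM. Of 20 glycolysis genes 8 rose, 7 fell and 5 did not pass, with a median of 0.01 and a camera adjusted p of 0.858. Pgam1 rose by 0.66 and Pkm, with split reads, by 0.54, while Ldhb fell by 0.92. Of 20 cholesterol synthesis genes 18 fell, 0 rose and 2 did not pass, with a median of -0.55. Dhcr7, a reductase late in the pathway, fell by 0.95 on the log2 scale. The cholesterol list's camera adjusted p was 3.92e-06, with adjusted p = 0.1405 with an estimated correlation. Of 32 ribosomal protein genes 8 rose, 9 fell and 15 did not pass, with a median of 0.02 and a camera adjusted p of 0.933. Rpsa fell by 0.31 and Rps2 by 0.30, while Rplp2 rose by 0.60; the last 2 have split reads. The sign of the glycolysis median changed when vehicle replicate 1 or carfilzomib replicate 1 was left out, to -0.04 and -0.02.

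All 26 tested proliferation genes fell, with a median of -0.85 and a range from -1.49 to -0.24. E2f1, a transcription factor of S-phase entry, fell by 1.49, and Mcm5, part of the replicative helicase, by 1.39 on the log2 scale. Proliferation genes had a camera adjusted p of 5.93e-16, with adjusted p = 0.1405 with an estimated correlation. Markers of fibroblasts, smooth muscle cells and macrophages, which can divide, had medians of -0.57, -1.03 and -2.09 in the same libraries. Of 17 inflammatory cytokines and NF-kB targets 10 fell, 4 rose and 3 did not pass; 12 fell when adjusted over the list alone. Vcam1, an adhesion molecule gene with split reads, fell by 0.98 and Il33 by 0.70, while the chemokine Ccl2 rose by 1.68. This list had a median of -0.34 and a camera adjusted p of 0.933. The median was -0.62 without vehicle replicate 2, -0.58 without carfilzomib replicate 1 and -0.68 without the low-count filter. Of 17 interferon-stimulated genes 7 fell, 5 rose and 5 did not pass, with a median of 0.01, a mean of -0.11 and a camera adjusted p of 0.933 in the direction Down. Irf1 rose by 0.28. Psmb10, a subunit of the immunoproteasome, had a log2 fold change of -0.31 with an edgeR adjusted p of 0.0106. That edgeR adjusted p was 0.062 without vehicle replicate 2 and 0.077 without carfilzomib replicate 1, with -0.27 in both, and the DESeq2 adjusted p was 0.1413. Without vehicle replicate 2, carfilzomib replicate 1 or carfilzomib replicate 2 the median of the interferon list was -0.05, -0.05 and -0.18.

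Markers of other cell types that such cultures can hold were measured as well. Of 22 matrix and fibroblast markers 19 fell, 1 rose and 2 did not pass, with a median of -0.57; 20 fell when adjusted over the list alone. Thy1 fell by 2.00 and Col3a1, a fibrillar collagen, from 3312 ± 26.3 to 1371 ± 19.3 CPM. Mmp2 had a log2 fold change of 0.10 with an edgeR adjusted p of 0.0328, which was 0.0676 without vehicle replicate 1, 0.215 without carfilzomib replicate 1 and 0.0862 without carfilzomib replicate 2, at 0.08, 0.09 and 0.12. The camera adjusted p was 2.83e-15, with adjusted p = 0.1405 with an estimated correlation. Of 10 smooth muscle and myofibroblast markers 9 fell and 1 rose, with a median of -1.03. Acta2, smooth muscle actin, with split reads, fell from 2340 ± 30.9 to 541.8 ± 8.88 CPM and Cnn1 had a log2 fold change of -1.70, while Des rose. The camera adjusted p was 2.55e-10, with adjusted p = 0.1405 with an estimated correlation.

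Of 12 macrophage and leukocyte markers 11 fell and 1 rose, with a median of -2.09, although 8 of the 12 had a mean under 10 CPM. Lyz2, lysozyme, with split reads, had a log2 fold change of -2.67 and Cd68 of -1.09, while Cd14, with split reads, rose by 0.56. The camera adjusted p was 9.73e-04, with adjusted p = 0.208 with an estimated correlation. Of 13 endothelial markers 5 fell, 3 rose and 5 did not pass, with a median of -0.35 and a camera adjusted p of 0.928. Ramp2 fell by 0.47 and Kdr, a receptor for vascular endothelial growth factor, by 0.40, while Egfl7, with split reads, rose by 0.54. The endothelial median was -0.19 without vehicle replicate 1 and -0.18 without carfilzomib replicate 2, and Ramp2 was at -0.31 without vehicle replicate 2. Of 10 mesothelial markers 4 rose, 3 fell and 3 did not pass, with a median of 0.08 and a camera adjusted p of 0.933; 4 fell when adjusted over the list alone. Krt8, a keratin, rose by 1.69 and Upk1b by 0.59, while Aldh1a2 fell by 1.43. The mesothelial median was 0.02 without carfilzomib replicate 2 and 0.24 over genes without split reads.

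Of 7 Schwann cell and neuron markers 2 rose, 2 fell and 3 did not pass, with a median of -0.30, against a camera direction of Up at an adjusted p of 0.933. Tubb3, a tubulin gene with split reads, rose by 0.80. Prph, peripherin, had a log2 fold change of 0.34 with an edgeR adjusted p of 0.0122, which was 0.0665 without carfilzomib replicate 1, at 0.32; the DESeq2 adjusted p was 0.1637. The median of the list was -0.16 without vehicle replicate 1. Of 4 erythroid markers 1 fell and 3 did not pass, with a median of -0.17 and a camera adjusted p of 0.928. The gene that fell was Hba-a1, a globin gene with split reads, at -0.32, for which DESeq2 gave an adjusted p of 0.107.

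**Figure D3:**
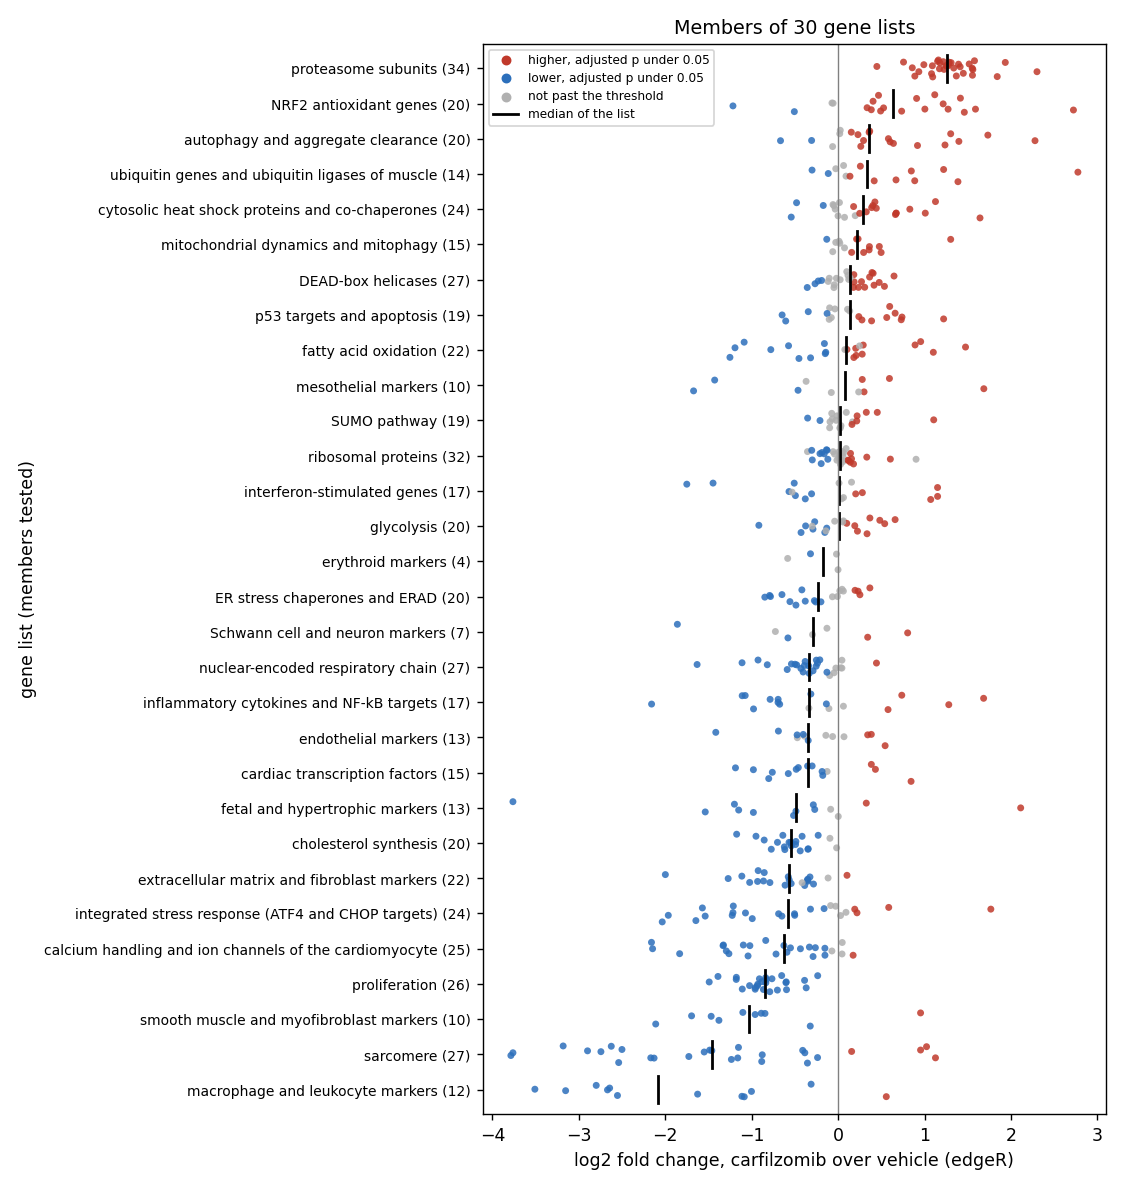
Log2 fold change, carfilzomib over vehicle, of each tested member of the 30 gene lists, ordered by the median, which is drawn as a black line. Red points rose and blue points fell at an edgeR adjusted p under 0.05, and grey points did not pass. The medians run from -2.09 for macrophage markers and -1.46 for the sarcomere to 1.26 for proteasome subunits.

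The 8 largest rises among genes with a mean of at least 10 CPM and separate groups began with Rbm11, an RNA-binding protein, which rose 36.7-fold from 0.62 ± 0.04 to 23.1 ± 0.44 CPM. Dync1i1, an intermediate chain of dynein, had a log2 fold change of 4.65, Tubb4a, a tubulin gene with split reads, 3.39, and Klhl40, a stabiliser of muscle thin filaments, 3.11. Uchl1 followed at 2.77, Osgin1 at 2.72, the transporter Abca2 at 2.49 and Atl1, an atlastin GTPase of the endoplasmic reticulum, at 2.45. The largest falls were led by Trim72, a membrane repair protein of muscle, which fell 18.1-fold from 56.9 ± 2.68 to 3.13 ± 0.31 CPM. Other large falls were those of Myh6 and Myh7, and Srl, sarcalumenin of the sarcoplasmic reticulum, was at -3.60. Lims2 was at -3.29, Tnni3 at -3.18 and Fbxl22, a muscle F-box protein with split reads, at -3.17.

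The authors' deposited table lists 6063 changed genes, 3181 higher and 2882 lower with carfilzomib. Of the 6052 genes of the authors' deposited table that were tested here, 6024 were called in the same direction, 28 were not called and 0 had the opposite sign. The authors' deposited table holds DESeq2 values and the calls here are those of edgeR, which called a further 2788 genes that do not stand in it. DESeq2 called 6489 genes here, of which 6048 stand in the authors' deposited table with the same direction. For Senp1 the authors' deposited table gives a log2 fold change of -0.35 and a q value of 0.00546, and for Ddx17 it gives 0.19 and 0.0182.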

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

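The fits over whole-count genes and with Myh6 and Myh7 summed were chosen after the data were seen. Calls of all genes were not compared in the test against 1.5-fold, in the fit with Myh6 and Myh7 summed, or with an estimated correlation, which concerns lists only. Each of the other alternatives gave an adjusted p to between 5916 and 8812 of the 8812 calls, and 0 of those changed sign; DESeq2 kept 6458 of them, voom 8736 and RLE factors 8801. The test against a fold change of 1.5 called 2028 genes, because it asks for a larger change. DESeq2 called 6489 genes, and leaving out 1 library gave 7360 to 7974. Library size alone moved the share of higher calls from 50.4% to 54.0% and the median of all genes by 0.033. Camera called 19 lists, 17 to 19 with 1 library left out and 0 with an estimated correlation, where 9 had an unadjusted p under 0.05 and the smallest adjusted p was 0.1405. No called list changed its camera direction in any alternative. With the replicate block edgeR called 8229 genes, 4146 higher and 4083 lower, of which 8170 were called before, and 19 lists. The deviations of equally numbered libraries had a correlation across genes of -0.0023 (Spearman -0.089), and the labels state no pairing. Of 102 named genes, 9 lost their call in some alternative: Ddit3, in 7 of its 11 alternatives, Phb2 in 5, and Ddx17, Camk2d, Ddx59, Psmb10, Mmp2, Prph and Hba-a1. Values that changed sign were of genes and lists that had not passed, and the cause was not tested. Nppa was at -0.00021 under DESeq2 and RLE factors and -0.0057 under the stricter filter, and -0.046 to 0.052 with 1 library left out. Hmox1 ranged from -0.12 to 0.010 with 1 library left out. The glycolysis list's median was -0.00040 under the stricter filter and -0.13 over whole-count genes, and -0.038 to 0.050 with 1 library left out. The list of interferon-stimulated genes was at -0.144 without a filter and -0.142 over whole-count genes, and -0.18 to 0.042 with 1 library left out. At this depth and number of libraries the simulation, in which far fewer genes changed than were called here, recovered 82% of 1.5-fold changes. That rate need not hold for these data, but small changes can be missed.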

Other observations

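The tests of fewer cardiomyocytes, of scaling, of fewer fibroblasts and of length in the stress lists, and all bootstrap intervals, were chosen after the results were seen, as were the genes named in this paragraph other than Psmb10. The values of the genes so chosen were not set against the alternatives. Each bootstrap interval came from resampling genes, taken as independent, and leaves out the spread between libraries. Of the immunoproteasome subunits, Psmb8 had a log2 fold change of -0.38 (edgeR adjusted p 0.0149) and Psmb9 of -0.51 (edgeR adjusted p 0.0131). Psmb10 was at -0.31, and its call was lost under DESeq2 (adjusted p 0.1413), without vehicle replicate 2 (0.062) and without carfilzomib replicate 1 (0.077). Psme1, a cap subunit induced by interferon, was at -0.56 (edgeR adjusted p 8.51e-08). Zfand2a, an arsenite-inducible partner of the proteasome with split reads, rose by 2.39. Keap1, the repressor of NRF2, rose by 1.17, Nfe2l1 by 0.24 and Nfe2l2, which encodes NRF2, by 0.24. Hsf2 rose by 0.80, while Hsf1 was at 0.09 and did not pass, with an edgeR adjusted p of 0.234. Flnc, filamin C, rose by 1.54 and Nrap by 0.72. Bag3, a partner of Hspb8, rose by 0.67.

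All 34 genes of the proteasome subunit list rose (list adjusted p = 0.1405 with an estimated correlation). A scaling factor shifts all genes of a library alike, and their median lay 1.261 above that of all tested genes (bootstrap 1.17 to 1.36), which argues against scaling as the whole cause. The trend of log2 fold change with gene length was slight, from -0.020 to 0.177 over all lengths, and its removal left their median at 1.249 (bootstrap 1.15 to 1.34), which argues against length as the whole cause. On the hypothesis that the rise may be part of a wider programme of proteasome supply, a list of assembly and shuttle factors was written before its values were seen, and it rose with a median of 0.5546, 14 of 19 higher and 1 lower. Its unadjusted camera p was 3.45e-08 at the preset correlation and 0.0267 with an estimated correlation. Adjusted over the hypothesis lists alone, the second value was 0.0401. The unadjusted camera p of the subunit list with an estimated correlation was 0.0159. The values go with the hypothesis, which was found and tested on the same data.

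Of 27 sarcomere genes 23 fell, by uneven amounts (list adjusted p = 0.1405 with an estimated correlation). The list median lay at -1.465 against that of all tested genes (bootstrap -2.17 to -0.88), and at -1.499 after removal of the slight length trend (bootstrap -2.32 to -1.04), which argues against scaling and length as the whole cause. Fewer cardiomyocytes as the whole cause would lower abundant members alike, where only cardiomyocytes express them, and raise markers of other cells. Not every member is so confined, since Des also stands in the list of smooth muscle markers. The range between the quartiles of the 22 members with at least 100 CPM was 2.026 (bootstrap 1.04 to 2.75), from -2.42 to -0.39. Of 7 other cell-type lists 6 had medians below 0, mesothelial markers being the exception at 0.08. Camera at the preset correlation called only the fibroblast, smooth muscle and macrophage lists lower. The endothelial, erythroid, and Schwann cell and neuron lists did not pass, with camera adjusted p of 0.928, 0.928 and 0.933. The median SE of the 22 abundant members was 0.044, far below the range between their quartiles. That range argues against fewer cardiomyocytes as the whole cause, for the members that only cardiomyocytes express. A partial loss of cardiomyocytes beside a lower level of some of these transcripts per cell stays open.

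Of 24 genes of the integrated stress response 16 fell and 4 rose, and of 20 chaperones and degradation factors of the endoplasmic reticulum 11 fell and 4 rose. With an estimated correlation the adjusted p = 0.1405 and 0.416, and that of the second list under camera was 0.0652 without vehicle replicate 1. The length trend was nowhere below -0.020, and after its removal their joint median was -0.3525 (bootstrap -0.629 to -0.087), which argues against length as the whole cause. Fewer fibroblasts as the whole cause cannot be told apart from lower levels per cell. The median of all 44 members lay 0.004745 above that of 5 fibroblast markers that are not matrix genes, with a bootstrap interval from -0.252 to 1.68, and members went both ways.

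Srf fell by 1.19 on the log2 scale, and 9 of 10 smooth muscle and myofibroblast markers fell while Des rose (list adjusted p = 0.1405 with an estimated correlation). A hypothesis is that targets of SRF and its partner MRTF in the actin cytoskeleton may have fallen more widely. In a list written before its values were seen 19 of 20 fell and 1 rose, with a median of -0.5622. Its unadjusted camera p was 7.12e-15 at the preset correlation and 0.0136 with an estimated correlation. Adjusted over the hypothesis lists alone, the latter was 0.0401. The unadjusted camera p of the smooth muscle list with an estimated correlation was 0.0515. Part of this list is expressed by smooth muscle cells and fibroblasts, whose markers also fell, so the values go with the hypothesis and do not separate it from a change in cell types. Uchl1, abundant in neurons, was among the 8 largest rises, as were Dync1i1, Tubb4a and Atl1, and a wider rise of neuronal genes was tested. The list tested does not hold these genes. A list of 18 tested neuronal cytoskeleton and vesicle genes had a median of -0.1626 (bootstrap -0.552 to 0.246), with 5 higher, 7 lower and 6 not past the threshold, and a camera p of 0.749. Several members had low counts. Among those called lower, Syt1 had a mean of 0.52 CPM, Gap43 1.00 and Nefl 1.58, and Stmn4, called higher, had 1.49. The genes of this list did not rise as a set. The bootstrap interval takes in both falls and rises, so the test cannot decide on a wider rise of neuronal genes. Members went both ways, so a rise of only some neuronal genes stays open.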
